A study of Mus musculus with 23 samples.

How the data were processed

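Total RNA of germ-cell preparations from testes of mice aged 14.5 days was labelled with biotin and hybridized to Affymetrix Mouse Gene 1.0 ST arrays, with 4 testes pooled per array, per the labels. There were 23 arrays of 7 genotypes. Each pool counts as a replicate. The labels number the arrays of a genotype but do not say whether pools came from separate litters, so p-values measure the spread between these pools. Per the series design text, the authors inspected intensity distributions and a principal component plot and left out a PWDxPWK array that stood apart, which leaves 2 of that genotype.

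The deposited table holds a log2 value for each of 25690 probe sets and 23 arrays. The base of the logarithm was taken from the range of the values, 1.17 to 13.96, and the background correction, normalization and software are not given in the sources used here. Medians of the arrays ran from 6.13 to 6.28, so their scale was close, but the centring step stays unknown. No scanner files were analysed here, so signal over background could not be judged for single probes.

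Probe sets were named through the platform annotation. Of them 20777 had 1 gene symbol, 232 had several and 4681 had none listed, and the last groups were not named. The Entrez IDs of 20696 matched the gene table of GRCm38.p6, which gave chromosomes, and 0 symbols changed. For 564 of 19661 genes with more than 1 probe set, the probe set with the highest mean over all arrays was used. The 25% of genes with the lowest mean were left out (log2 below 5.125), which left 14745.

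The values were analysed with R 4.3.3 and limma 3.58.1. A linear model with 7 genotype means was fitted to all 23 arrays (16 residual degrees of freedom), with moderated variances and without trend. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and differences are in log2 units with the model's standard error. The comparisons were PWDxB6 against B6xPWD, each of these hybrids against the mean of PWD and B6, PWD against B6, B6xBALB/C against BALB/CxB6, PWDxPWK against PWD, and the reciprocal minus the parental difference. Each hybrid was also compared with the parent carrying the same X. X-linked genes as a set were tested with camera at a preset correlation between genes of 0.01 and at an estimated correlation. The score of each array, the mean of X-linked minus the mean of autosomal genes, was compared by two-sided exact permutation tests. PWDxB6 and B6xPWD were each compared with the 17 other arrays.

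The 20 gene lists, with 429 members of which 365 were on the array and 334 tested (31 were dim), covered spermatogonia, synapsis and cohesin, recombination, sex-body silencing factors, pachytene spermatocytes, spermatids, the piRNA pathway, X-linked germ cell genes, Y-linked genes, imprinted genes, DNA damage and apoptosis, interferon response, Sertoli, Leydig, peritubular and stromal, macrophage, endothelial and red blood cells, stress of dissociation, and control genes. A gene may be on 2 lists. Named genes were the 10 largest rises and falls past the threshold without overlap of replicates for the reciprocal and mid-parent comparisons, 5 each for the others, up to 4 members of each list with the smallest p, Prdm9 and the Y-linked genes. For the interaction, the 5 and 5 X-linked genes were taken without the overlap condition. The 14 X-linked genes higher in both hybrids, and other members named as examples, were chosen after their values were seen. Lists, comparisons, the rule and the alternatives were set before the data were examined.

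The alternatives were no dim filter and a stricter one, quantile normalization, centring on the autosomal median, the mean of probe sets, trended and robust variances, array weights, a block for the replicate number, a fit of only the groups compared, the intra-subspecific F1s as reference, the mid-parent on the linear scale, autosomal genes alone, B6xBALB/C replicates 1 to 3 and 4 to 6, and each array left out in turn. The replicate block was fitted to replicates 1 to 3 only, without B6xBALB/C replicates 4 to 6. A pachytene score as a covariate, the mean of the autosomal members of the pachytene list on each array relative to all arrays, was chosen after seeing the data. Means of synapsis and recombination genes and of somatic markers, made the same way, were used as covariates only for the X-linked genes higher in both hybrids. The model was tested on simulated arrays with real means and spreads and 200 changed genes. For the reciprocal comparison over 14745 genes, 46% of 50 genes changed by 0.5 and 95% of 100 changed by 1 were recovered, and 4% of calls were false. Camera called a simulated X shift of 0.1 in 20 of 20 runs and an unshifted X in 0 of 20. Genes were simulated as independent, so this does not test the preset correlation, while the estimated one for the X was 0.084. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.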

Results

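Gene expression was measured with Affymetrix Mouse Gene 1.0 ST arrays in germ-cell preparations from testes of mice aged 14.5 days, an age at which the most advanced germ cells of the first wave are in meiotic prophase. The 23 arrays fell into 7 genotypes, each array holding RNA pooled from 4 testes. PWD (3 arrays) is an inbred strain of the mouse subspecies Mus musculus musculus, and B6 (3 arrays) is a laboratory strain of mainly Mus musculus domesticus origin. The reciprocal crosses between them, PWDxB6 (3 arrays) and B6xPWD (3 arrays), were set beside crosses within a subspecies: PWDxPWK (2 arrays), B6xBALB/C (6 arrays) and BALB/CxB6 (3 arrays). Names give the female first, by convention, so a hybrid male carries the X of the first strain and the Y of the other. Males of the PWDxB6 direction are known from the field as sterile with meiotic arrest. Of 19661 genes on the array, 14745 passed a filter on dim signal and were tested, 474 of them on the X, 8 on the Y and 14221 on autosomes. The medians of the arrays lay between 6.13 and 6.28 on the log2 scale, and the number of arrays limits the precision.

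The strain of the mother could be read from X-linked genes. Of 89 X-linked genes that differed between PWD and B6, 70 differed in the same direction between PWDxB6 and B6xPWD, and all 23 that passed the test in both comparisons had the same direction. Across the 474 X-linked genes the reciprocal difference correlated with the parental difference at r = 0.51, against 0.26 across 14221 autosomal genes. Genes are not independent replicates, and both comparisons use separate arrays. The 8 Y-linked genes gave r = -0.10, too few genes to place the father.

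The reciprocal hybrids, which carry different X chromosomes, differed in X-linked and autosomal genes. Fgf2, a fibroblast growth factor, had a mean log2 level of 7.48 ± 0.30 (SD, n = 3) in PWDxB6 and 6.15 ± 0.20 (SD, n = 3) in B6xPWD, a difference of 1.32 (SE 0.148, adjusted p = 2.36e-05). The X-linked genes Tsx (1.19), Zcchc12 (1.11), Pcyt1b (1.01) and Ccnb3 (0.92), a cyclin expressed in early meiosis, were higher in PWDxB6, as were Defb15 (1.32), a beta-defensin, Map3k7cl (1.01), Slc16a14 (0.93), Cyp2d10 (0.89) and Cyp26b1 (0.88), an enzyme that degrades retinoic acid. Lower in PWDxB6 were 1700006A11Rik (-3.63), Gm10619 (-2.61), 4933440M02Rik (-2.18), Flacc1 (-1.96), Morc2b (-1.76), Gm10505 (-1.70) and Rpl39l (-1.65), a testis-expressed ribosomal protein gene. The X-linked Gm648 (-2.20), Magea5 (-1.87) and Magea6 (-1.56) were lower as well, the last pair being members of a melanoma antigen family whose near-identical copies may share probes, so single members are uncertain. Calls were lost in 4 of 16 alternatives for Gm10505 and Rpl39l, 4 of 16 for Cyp26b1, 3 of 16 for Gm10619, 3 of 15 for Flacc1 and 4933440M02Rik, and 2 of 15 for Morc2b and Map3k7cl, mostly without PWDxB6 replicate 1 or 3 or B6xPWD replicate 2. With a pachytene score as a covariate the differences shrank to -2.18 for 1700006A11Rik, -1.336 for Gm10619, -1.143 for 4933440M02Rik, -1.033 for Flacc1, -1.005 for Morc2b, -0.877 for Gm10505 and -1.10 for Rpl39l, the last no longer past the threshold. In all, 418 genes passed the limma test, 196 higher and 222 lower in PWDxB6, and with the arrays centred on the median autosomal gene the split was 108 higher and 327 lower. The X-linked share was 11.8% of 474 genes, 22 higher and 34 lower, against 2.55% of 14221 autosomal genes. The count fell to 54 without PWDxB6 replicate 3, 81 without PWDxB6 replicate 1 and 59 without B6xPWD replicate 2, to 207 (40 higher and 167 lower) with those groups fitted alone, and to 137 with the pachytene score as a covariate. It rose to 4635 (2479 and 2156) with array weights.

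Lists of meiotic genes lay lower in PWDxB6 than in B6xPWD. Of 19 measured piRNA pathway genes, which silence transposons in germ cells, Asz1 fell (-0.87, SE 0.212, adjusted p = 0.0301), and 9 were lower when adjusted over the list alone. The median of that list was -0.45 (camera adjusted p = 1.56e-07), with adjusted p = 0.57 with an estimated correlation. Of 22 meiotic recombination genes, 3 fell over all genes and over the list alone: Ccnb1ip1 (-0.80), Tex15 (-0.42) and Rec114 (-0.60). The list's median was -0.26 (camera adjusted p = 0.000111), with adjusted p = 0.57 with an estimated correlation. Of 29 genes of pachytene spermatocytes, 1 rose (Ccnb3), none fell over all genes and 6 fell when adjusted over the list alone, with a median of -0.31 (camera adjusted p = 0.000111), and adjusted p = 0.737 with an estimated correlation. The mean of these 29 genes, relative to all arrays, was -0.301 ± 0.149 (SD, n = 3) in PWDxB6 and 0.167 ± 0.222 (SD, n = 3) in B6xPWD. Of 18 synapsis and cohesin genes 1, Meioc (-0.59), fell, with a median of -0.15 (camera adjusted p = 0.00674), and adjusted p = 0.79 with an estimated correlation. That call was lost without PWDxB6 replicate 3 (adjusted p = 0.0564) or B6xPWD replicate 3 (adjusted p = 0.0631). Of 18 X-linked germ cell genes 2 fell, Magea5 and Rhox13 (-0.90), over all genes and over the list alone (camera adjusted p = 0.103). Among 26 imprinted genes, Nnat was lower (-0.92, SE 0.125, adjusted p = 0.000343), and 3 were higher and 4 lower when adjusted over the list alone, the list as a whole having camera adjusted p = 0.952. Mgp (-0.80) fell while Des (0.55) and Cnn1 (0.56), contractile genes of peritubular cells, rose, and 5 of 17 peritubular and stromal genes rose and 1 fell when adjusted over the list alone. That list had 13 positive differences (median 0.19, camera adjusted p = 0.103), endothelial genes 11 of 13 (0.20, camera adjusted p = 0.136) and Sertoli cell genes 19 of 24 (0.09, camera adjusted p = 0.285), the last pair with 0 calls over the list alone. The median of all genes was itself 0.03. With arrays centred on the median autosomal gene the positive counts of these 3 lists were 12, 11 and 14, and with quantile normalization 13, 10 and 20. Bak1 (0.57) rose while Trp53inp1 (-0.53) fell among 22 genes of DNA damage and apoptosis. Single members also fell among immune genes (H2-Ab1, -0.52) and stress genes (Ier3, -1.16). Spermatogonia, sex-body silencing factors, spermatid, interferon response, Sertoli cell, Leydig cell, endothelial, red blood cell, Y-linked and control genes had 0 members past limma's threshold among all genes, where 3112 genes had an unadjusted p under 0.05. Prdm9, the meiotic histone methyltransferase known as a hybrid sterility gene, differed by 0.22 (SE 0.159, adjusted p = 0.447), and by 0.77 between PWD and B6 (SE 0.159, adjusted p = 0.00158).

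Against the mean of both parental strains, PWDxB6 had raised sex-linked genes and lowered interferon genes. The Y-linked zinc-finger genes Zfy1 and Zfy2, near-identical copies that may share probes, rose by 1.37 (SE 0.197, adjusted p = 0.000367) and 1.38 (SE 0.167, adjusted p = 4.15e-05). Zfy2 stood at 8.29 ± 0.39 in PWDxB6, 7.20 ± 0.06 in PWD and 6.63 ± 0.18 in B6 (SD, n = 3 each). X-linked genes that rose were 1700080O16Rik (2.47), Gm9 (1.74), Ccnb3 (1.65), Dcaf8l (1.43), Cfap47 (1.24) and Nxt2 (1.23), and on autosomes Defb15 (2.02) and Srgap1 (1.13) rose. Those that fell were Aym1 (-1.49), Ddx60 (-0.99), Rnf213 (-0.71), Bcan (-0.70), Oasl2 (-0.57), Thada (-0.54), Pcnx3 (-0.48) and Usp18 (-0.46), with the X-linked Clcn5 (-0.69) and Slc9a7 (-0.43). The calls of Slc9a7, Bcan and Usp18 were lost in 12 of 21, 10 of 21 and 7 of 20 alternatives. Of 99 genes past the limma test, 75 were higher and 24 lower, with 29 of the higher and 5 of the lower on the X. The X held 7.17% called genes against 0.443% of autosomal genes. A hybrid male carries the X and the Y of 1 strain each, so for sex-linked genes the mid-parent holds part of the parental difference. Against PWD, with the same X, the shares were 4.01% and 2.24%. In that comparison the autosomes are not matched, so the autosomal share holds part of the parental difference and is no like baseline for the X. The count was 30 without PWDxB6 replicate 2 and 62 without replicate 3, 41 with autosomal genes tested alone, 174 (91 higher and 83 lower) with the groups compared fitted alone, 212 (124 and 88) with array weights, 239 (140 and 99) with a replicate block and 483 (305 and 178) with the pachytene score as a covariate.

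Of 18 X-linked germ cell genes, 5 rose in PWDxB6 against the mid-parent and 8 when adjusted over the list alone, among them Tsga8 (0.84), Tktl1 (0.86), Fmr1 (0.59) and Usp26 (0.54). The list gave camera adjusted p = 1.69e-11, and adjusted p = 0.0878 with an estimated correlation. Against PWD, with the same X, its median was 0.137 (camera adjusted p = 0.000101 at the preset correlation). Of the 8 Y-linked genes 2 rose, and 4 rose and 1 fell when adjusted over the list alone, the remaining members being Usp9y (0.59, adjusted p = 0.0823), Eif2s3y (0.29), Uba1y (0.20), Sry (0.06), Uty (0.00) and Kdm5d (-0.37). That list gave camera adjusted p = 0.000137, and adjusted p = 0.108 with an estimated correlation. Of 18 interferon response genes 3 fell, Oasl2, Usp18 and Ddx58 (-0.58), an RNA sensor, and 4 fell when adjusted over the list alone (camera adjusted p = 2.27e-05, adjusted p = 0.0288 with an estimated correlation). Of 13 endothelial genes 0 passed over all genes in limma and 1 fell over the list alone, with a median of -0.19 (camera adjusted p = 0.00207, adjusted p = 0.767 with an estimated correlation, and adjusted p = 0.169 without PWDxB6 replicate 2). Single members rose in the lists of spermatogonia (Stra8, 0.60) and of DNA damage and apoptosis (Pmaip1, 0.86, SE 0.108, adjusted p = 6.87e-05), a gene that promotes apoptosis. Among all genes 1764 had an unadjusted p under 0.05.

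B6xPWD departed from the mid-parent in more genes. Zfy1 and Zfy2 rose by 1.52 (SE 0.197) and 1.53 (SE 0.167), and so did the X-linked Magea6 (2.05), Magea5 (1.82), 1700080O16Rik (1.71), Gm648 (1.64) and Magea3 (1.46). Autosomal genes that rose were Pdha2 (1.54), the testis form of a pyruvate dehydrogenase subunit, Cox7b2 (1.51) and Rpl39l (1.49). Those that fell were Tpcn1 (-0.88), Tubb3 (-0.85), St8sia2 (-0.82), Tgfb1 (-0.81), Notch1 (-0.80), Syne1 (-0.80), Cyp26b1 (-0.80), Adamts5 (-0.77), 9530091C08Rik (-0.76) and Fbn2 (-0.76), Tgfb1 and Notch1 being signalling genes of many cell types. Of 2135 genes past the limma test 1148 were higher and 987 lower, and 1371 and 617 with arrays centred on the median autosomal gene. The X held 100 higher and 28 lower, 27.0% of its genes against 14.1% of autosomal genes. Against B6, with the same X, the shares were 23% and 16.8%, the latter holding part of the parental difference, since autosomes are not matched there. The count was 389 without B6xPWD replicate 2, 1408 without replicate 1, 1055 with the pachytene score as a covariate and 5967 (2782 higher and 3185 lower) with array weights. With the intra-subspecific F1s as reference it was 282, and that of PWDxB6 130.

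In B6xPWD 11 of 18 X-linked germ cell genes rose, and 13 when adjusted over the list alone, with Tsga8 (0.75), 1700013H16Rik (1.18), Rhox13 (0.98) and Taf7l (0.78) as examples (camera adjusted p = 9.24e-11, adjusted p = 0.108 with an estimated correlation). Of 8 Y-linked genes 5 rose and 6 over the list alone, with Eif2s3y at 0.56, Usp9y at 0.78 and Uba1y at 0.65 (camera adjusted p = 1.79e-05, adjusted p = 0.108 with an estimated correlation). Meiotic lists had risen members: 5 of 18 for synapsis and cohesin (Sycp3, 0.87; Rad21l, 0.47), 4 of 22 for recombination (Rec114, 0.69; Tex11, 0.59), 5 of 29 for pachytene spermatocytes (Ccnb3, 0.74; Cdkn3, 0.54) and 3 of 19 for the piRNA pathway (Asz1, 0.85; Tdrkh, 0.47). Adjusted over the list alone these counts were 5, 4, 5 and 4. Camera adjusted p was 0.000592, 0.00161, 0.000503 and 0.000142, and 0.470, 0.470, 0.511 and 0.470 as adjusted p with an estimated correlation. Somatic lists had fallen members: 5 of 13 endothelial (Tie1, -0.38; Cdh5, -0.68), 5 of 24 Sertoli cell (Wt1, -0.58; Amh, -0.56), 4 of 17 peritubular and stromal (Col1a1, -0.70; Pdgfrb, -0.49) and 2 of 11 Leydig cell genes (Vcam1, -0.76; Cyp11a1, -0.64), Mgp rising by 0.75. Over the list alone 9, 8, 4 and 4 fell. Of these the first 3 had camera adjusted p of 0.000229, 0.0251 and 0.0302, and adjusted p = 0.343, 0.640 and 0.572 with an estimated correlation. Of 18 interferon genes 5 fell and 1 rose, Ddx58 (-0.66) and Ifi27 (0.49) being examples (camera adjusted p = 0.00268, adjusted p = 0.115 with an estimated correlation). Imprinted genes moved both ways, with Cdkn1c (0.64) and Nnat (0.47) higher and Peg10 (-0.74) and Dlk1 (-0.49) lower among 4 risen and 2 fallen members. Of 22 DNA damage genes 5 rose and 3 fell, and Pmaip1 rose by 1.00. Among 7 control genes Hprt (0.65) and Tbp (0.43) rose, and 4 over the list alone (camera adjusted p = 0.0253, adjusted p = 0.285 with an estimated correlation). Without B6xPWD replicate 3 the control list had adjusted p = 0.0548 and recombination adjusted p = 0.0517. The stromal list had adjusted p = 0.0511 without PWD replicate 3, 0.0867 without B6 replicate 2, 0.0843 without B6xPWD replicate 2 and 0.0532 without B6xPWD replicate 3. Over all genes 3 of 21 spermatogonial genes rose, 2 of 19 stress genes rose and 1 of 15 macrophage genes rose, while sex-body silencing factors, spermatid and red blood cell genes had 0 past limma's threshold, where 4664 genes had an unadjusted p under 0.05.

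The departures of both hybrids from the mid-parent overlapped, and they share the parental arrays. Of the 75 and 1148 higher genes 48 were shared, against 5.84 for independent lists, and of the 24 and 987 lower genes 8 were shared against 1.61. The log2 differences correlated at r = 0.357 across genes, while unchanged groups simulated against the same parents gave a mean of 0.335 and up to 0.364 in 100 draws, so this correlation lay within the range without change. The covariance was 0.0174 against 0.00544 simulated. The parents cannot be split into parts with at least 2 arrays each, so part of the excess may come from them.

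X-linked genes were compared with the parent that carries the same X, where differences in probe sequence between the X chromosomes cancel. Against PWD, 17 X-linked genes were higher and 2 lower in PWDxB6, led by 1700080O16Rik (1.77), Gm9 (1.5), Ccnb3 (1.02), Dcaf8l (1.00) and Fndc3c1 (0.89), with Taf1 (-0.51), its call lost in 8 of 16 alternatives, and Il13ra1 (-0.45) lower. Against B6, 92 were higher and 17 lower in B6xPWD, led by 1700080O16Rik (2.40), Magea6 (2.02), 3830403N18Rik (1.91), Magea3 (1.82) and Magea5 (1.78), with Nrk (-0.78), Nudt10 (-0.71), Mamld1 (-0.70), Gpc4 (-0.67) and Slc38a5 (-0.60) lower. The genes higher in both comparisons, which share no arrays, were 14 against 3.30 for independent lists: 1700013H16Rik, 1700080O16Rik, Ccnb3, Cfap47, Dcaf8l, Efhc2, Gm773, Gm9, Maoa, Nxt2, Prame, Tktl1, Tsga8 and Tsr2. Across X-linked genes the 2 sets of differences correlated at r = 0.51, and across autosomal genes at -0.07. On autosomes both sets hold part of the parental difference, with opposite signs. This lowers r there, so -0.07 is no baseline for the X. Against the mid-parent r was 0.42 for the X and 0.34 for autosomes, where shared parental arrays raise both.

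Markers of cell types moved in B6xPWD against B6 beside the X-linked genes. Of somatic markers, 6 of 13 endothelial, 5 of 11 Leydig cell, 5 of 17 peritubular and stromal, 4 of 24 Sertoli cell and 5 of 15 macrophage genes fell, and 8, 5, 6, 5 and 8 when adjusted over the list alone, while 1 stromal and 2 macrophage genes rose. Camera adjusted p was 0.000198, 0.0123, 0.00814, 0.00629 and 0.0330, and 0.318, 0.318, 0.483, 0.535 and 0.483 as adjusted p with an estimated correlation. Of meiotic genes, 5 of 18 for synapsis and cohesin and 8 of 22 for recombination rose, and 5 and 10 over the list alone, where 1 recombination gene fell (camera adjusted p = 0.00067 for both, adjusted p = 0.483 with an estimated correlation). The list call was lost for stromal genes without B6 replicate 2 (adjusted p = 0.0611), for Leydig cell genes without B6xPWD replicate 3 (adjusted p = 0.0626), and for macrophage genes without B6 replicate 2, B6 replicate 3 or B6xPWD replicate 3 (adjusted p = 0.0828, 0.116 and 0.123). In PWDxB6 against PWD 1 macrophage gene rose and 1 recombination gene fell, the latter 4 over the list alone, and these 7 lists had camera adjusted p of 0.148 or more. Without 1 array some passed: macrophage without PWDxB6 replicate 2 (median 0.25, camera adjusted p = 0.0066), recombination without PWD replicate 1 (-0.13, camera adjusted p = 0.0149) and endothelial without PWDxB6 replicate 3 (-0.24, camera adjusted p = 0.0159). The pachytene list had a median of 0.17 in that comparison with all arrays (camera adjusted p = 0.0560). It passed without PWDxB6 replicate 3 (0.19, camera adjusted p = 0.00948), while without PWDxB6 replicate 2 its median was 0.06 (camera adjusted p = 0.202).

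**Figure D1:**
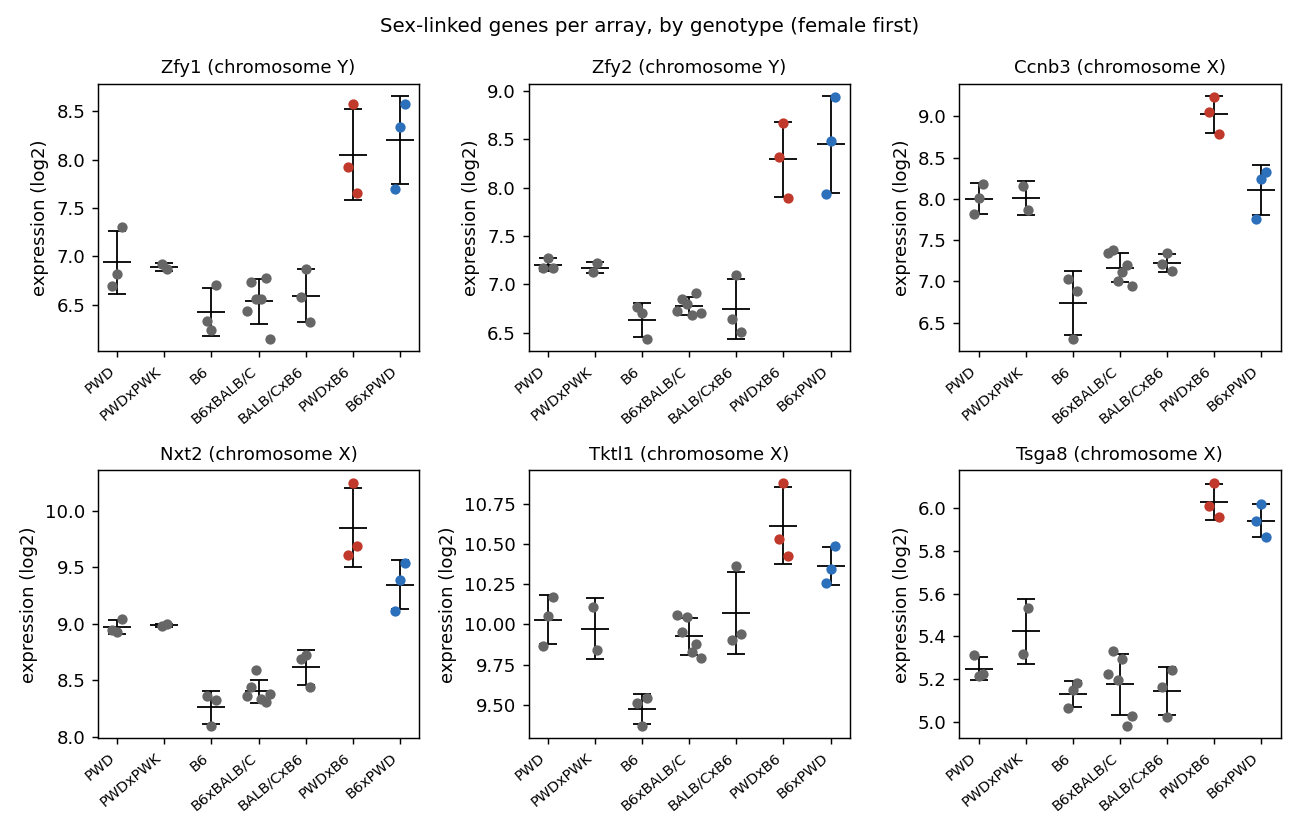
Log2 expression of 2 Y-linked and 4 X-linked genes on each of 23 arrays, by genotype, with a point per array, the mean as a horizontal bar and the SD as whiskers. Tsga8 has means of 6.03 in PWDxB6 and 5.94 in B6xPWD, against 5.25 in PWD and 5.13 in B6.

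As a whole the X moved little. Its median log2 difference lay 0.04 above the autosomal median in PWDxB6 against PWD (camera p = 0.00291, p = 0.280 with an estimated correlation) and 0.06 above it in B6xPWD against B6 (camera p = 0.00335, p = 0.287 with an estimated correlation), and without B6xPWD replicate 3 the last was 0.02 (p = 0.195). Between the reciprocal hybrids the shift was -0.03 (camera p = 0.121 at the preset correlation). It was -0.06 without B6xPWD replicate 1 (p = 0.0111 at the preset correlation), -0.05 without replicate 2 (p = 0.0277 at the preset correlation) and 0.02 without replicate 3, and -0.07 with the pachytene score as a covariate (p = 0.000443 at the preset correlation). The largest shift of the X was in the control cross, B6xBALB/C against BALB/CxB6, at -0.12 (camera p = 3.99e-10, p = 0.0319 with an estimated correlation). The mean of X-linked genes minus that of autosomal genes on each array was 0.121 ± 0.0203 (SD, n = 3) in PWDxB6 and 0.169 ± 0.0960 (SD, n = 3) in B6xPWD, against 0.0217 ± 0.0701 (SD, n = 17) in the other genotypes. The latter ranged from -0.0373 ± 0.0720 in B6xBALB/C (n = 6) to 0.10 ± 0.0337 in BALB/CxB6 (n = 3). Two-sided exact permutation tests gave p = 0.0237 (adjusted 0.0355) for PWDxB6 and p = 0.00526 (adjusted 0.0158) for B6xPWD against those 17 arrays, over 3 tests. Those arrays are of 5 genotypes that differ in this score, so the p-values treat arrays as exchangeable and do not measure the spread between genotypes. An exact permutation test between both hybrids gave p = 0.7, where 0.1 is the smallest value possible. The p for B6xPWD was 0.0819 in the exact permutation test without its replicate 3, and that for PWDxB6 0.0819 without its replicate 2 and 0.0643 without replicate 3.

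**Figure D2:**
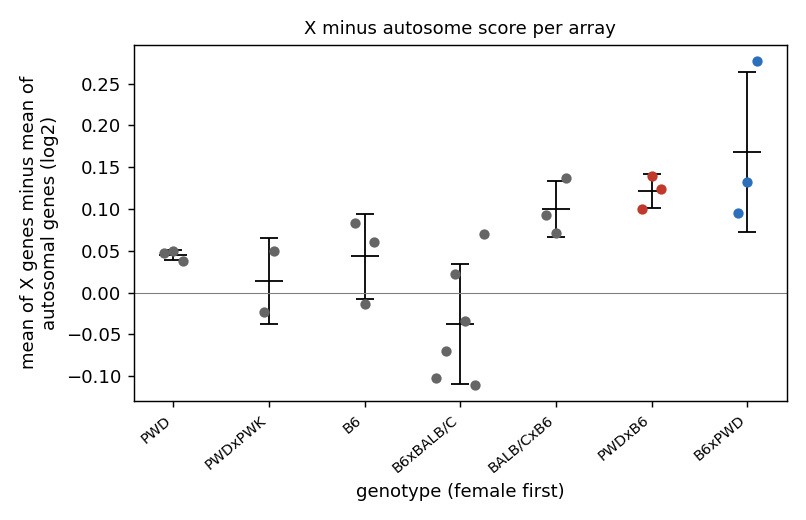
Mean log2 of 474 X-linked genes minus that of 14221 autosomal genes on each array, by genotype, with a point per array, the mean as a horizontal bar and the SD as whiskers. The highest array is B6xPWD replicate 3 at 0.277, and BALB/CxB6 (mean 0.10) overlaps with both hybrids.

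For X-linked genes, the reciprocal difference was also compared with the parental difference, an interaction in which effects of the X itself cancel. Nudt10 (1.07), Tsx (0.79), Porcn (0.76), Mpp1 (0.74) and Slc38a5 (0.71) had a positive interaction. For Tsx the difference was 1.19 between the hybrids and 0.40 between the parents, while for Porcn it was -0.20 and -0.96, a smaller difference in the hybrids. Magea5 (-1.80), 3830403N18Rik (-1.56), Magea6 (-1.50), Magea3 (-1.13) and Bex1 (-1.09, SE 0.280, adjusted p = 0.0169) had a negative interaction. The calls of Slc38a5 and Magea3 were lost in 11 of 22 and 9 of 21 alternatives. That of Tsx was lost in 7 of 22, those of 3830403N18Rik and Magea6 in 5 of 21 each and that of Magea5 in 4 of 21. Bex1 lost its call in 2 of 22, Mpp1 in 1 of 21, and Porcn and Nudt10 in 0 of 22. Of the 1328 genes past the limma test 28 were X-linked, 8 higher and 20 lower, and the median of the X lay at -0.02 against autosomes (camera p = 0.389 at the preset correlation) and at 0.06 without B6xPWD replicate 3. The count was 823 without PWD replicate 2, 856 and 788 without PWDxB6 replicates 1 and 3, 820 without B6xPWD replicate 2, 3314 with array weights and 2085 with the pachytene score as a covariate. On autosomes, where both hybrids have the same genotype, the contrast holds the parental difference with the sign turned beside any reciprocal difference, and the 2 parts were not separated.

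Between the parental strains, interferon genes were higher in PWD and several genes of spermatocytes lower. Mx2, an antiviral GTPase, differed by 2.08 (SE 0.209, adjusted p = 2.32e-07), and Ddx58 (1.09), Irf7 (1.05) and Irf9 (0.75) were higher too. Of 18 interferon genes 8 were higher and 1 lower, and 12 and 1 when adjusted over the list alone (camera adjusted p = 5.73e-05, adjusted p = 0.0312 with an estimated correlation). The largest differences were Vnn1 (2.93), Lgals3bp (2.65), Kcnc2 (2.63), Cadps (2.23) and Gask1a (2.19), higher in PWD, and Trim12a (-4.43), 1700006A11Rik (-3.60), 2610524H06Rik (-3.13), Gm10619 (-3.07) and 1700006J14Rik (-2.65), lower. In the pachytene list 5 of 29 genes were lower and 1 higher, and 9 and 1 when adjusted over the list alone, with Mns1 at -1.71, Clgn at -2.15 and Ccnb3 at 1.27 (camera adjusted p = 0.000885, adjusted p = 0.687 with an estimated correlation). In the piRNA pathway 6 of 19 were lower, and 8 over the list alone, with Mov10l1 at -0.61 (camera adjusted p = 0.000885, adjusted p = 0.687 with an estimated correlation). In the macrophage list 7 of 15 were lower and 2 higher, and 9 and 3 over the list alone, with Mrc1 at -1.15 and Cd74 at 0.97 (camera adjusted p = 0.00865, adjusted p = 0.687 with an estimated correlation). Of 18 X-linked germ cell genes 4 were higher, over all genes and over the list alone, with Fmr1 at 0.48 (camera adjusted p = 0.0246, adjusted p = 0.687 with an estimated correlation). That call was lost without PWD replicate 3 (adjusted p = 0.0833) or B6 replicate 2 (adjusted p = 0.225). In all 2719 genes passed the limma test, 1533 higher and 1186 lower in PWD, and 1802 without PWD replicate 2. The array was designed on the B6 sequence, so a lower signal in PWD can come from a mismatch under the probes.

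The interferon genes of the hybrids lay near the level of B6. The mean of the list, relative to the mean of all arrays, was 0.363 ± 0.106 in PWD (SD, n = 3), 0.494 ± 0.0540 in PWDxPWK (SD, n = 2), -0.111 ± 0.0170 in B6 (SD, n = 3), -0.0580 ± 0.0300 in PWDxB6 (SD, n = 3) and -0.0720 ± 0.0420 in B6xPWD (SD, n = 3). Against PWD, 8 of 18 interferon genes were lower in PWDxB6, and 10 lower and 1 higher when adjusted over the list alone, with Mx2 at -1.56 and Ddx58 at -1.13 (camera adjusted p = 3.77e-11, adjusted p = 0.000625 with an estimated correlation). Against B6, 2 were higher and 1 lower in B6xPWD, and 2 and 2 over the list alone, with Mx2 at 0.70 and Oasl2 at -0.39 (camera adjusted p = 0.940).

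**Figure D3:**
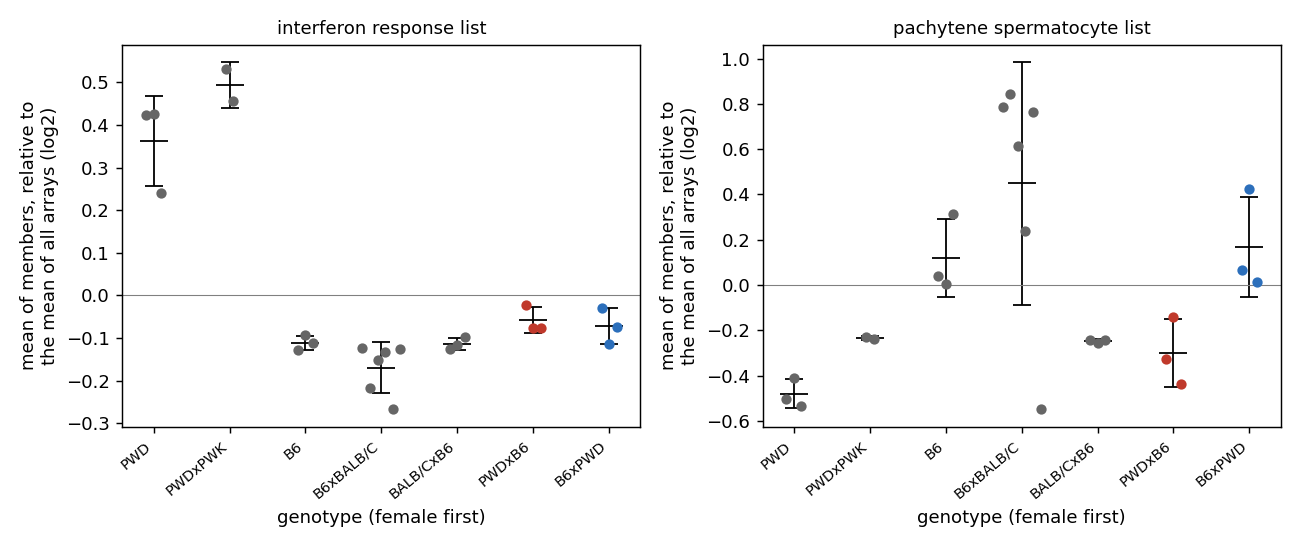
Mean log2 of the interferon response list (18 genes) and of the pachytene spermatocyte list (29 genes) on each array, relative to the mean of all 23 arrays, by genotype, with a point per array, the mean as a horizontal bar and the SD as whiskers. Interferon means are 0.363 in PWD and 0.494 in PWDxPWK and below 0 in the other genotypes, and the B6xBALB/C arrays range from -0.549 to 0.842 in the pachytene list.

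The control reciprocal cross within a subspecies differed in 56 autosomal and 7 X-linked genes among 65. Cfap74 (1.21), the X-linked Klhl4 (1.13), 4933414I15Rik (1.08), Atf3 (1.05), a stress-induced transcription factor, and Gtf2a1l (1.03) were higher in B6xBALB/C than in BALB/CxB6. Lower were Anp32e (-0.63), Rps19-ps3 (-0.65) and the X-linked 4930595M18Rik (-0.79), Chrdl1 (-0.69) and Rhox13 (-0.67). With those groups fitted alone 0 genes passed in limma, and the calls of 4933414I15Rik and Gtf2a1l were lost in 13 of 20 alternatives, Cfap74 in 12 of 20, Anp32e and Rps19-ps3 in 11 of 21, and Atf3 and Rhox13 in 10 of 21. The 65 genes past the limma test were 53 higher and 12 lower, and 63 and 29 with the arrays centred on the median autosomal gene, 1 and 2 with quantile normalization. In the pachytene list 0 of 29 genes passed over all genes in limma and 17 rose over the list alone, with a median of 0.57 (camera adjusted p = 9.23e-17, adjusted p = 0.282 with an estimated correlation), where 2095 genes had an unadjusted p under 0.05. In the piRNA pathway Tdrd6 (1.70) rose and 6 rose and 1 fell over the list alone (camera adjusted p = 3.72e-08, adjusted p = 0.456 with an estimated correlation). Of 19 stress genes 1 rose (Atf3) and 8 over the list alone (camera adjusted p = 9.87e-09, adjusted p = 0.282 with an estimated correlation), and Sertoli cell genes had a median of -0.22 with 0 past the threshold (camera adjusted p = 9.72e-05, adjusted p = 0.607 with an estimated correlation). The X-linked germ cell list had a median of -0.18 with Rhox13 lower (camera adjusted p = 8.89e-06, adjusted p = 0.425 with an estimated correlation). The mean of the 29 pachytene genes, relative to all arrays, was 0.449 ± 0.536 in B6xBALB/C (SD, n = 6) and -0.247 ± 0.00700 in BALB/CxB6 (SD, n = 3). The count was 1011 without B6xBALB/C replicate 6, 218 without replicate 4, between 3 and 7 without each of the others of that genotype, between 1 and 8 without each BALB/CxB6 array, and 1 with the pachytene score as a covariate.

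PWDxPWK and PWD, both from Mus musculus musculus, differed in 1 gene past the limma test, Aldh7a1 (0.66, SE 0.103, adjusted p = 0.0207), with 419 genes at an unadjusted p under 0.05. Aldh7a1 stood at 9.36 in PWDxPWK (n = 2) and 8.69 ± 0.08 in PWD (SD, n = 3), and its call was lost in 6 of 15 alternatives, without each of the 5 arrays in turn and with the groups compared fitted alone, where 3 other genes passed, all lower. Without a PWDxPWK array 1 array of that genotype is left, which is assumed to vary like the other genotypes. Of 19 stress genes 0 passed over all genes in limma and 3 fell over the list alone, with a median of -0.36 (camera adjusted p = 3.25e-12, adjusted p = 0.133 with an estimated correlation). The lists of the piRNA pathway (median 0.20), pachytene spermatocytes (0.19) and interferon response (0.14) lay higher and that of peritubular and stromal cells (-0.21) lower, with 0 members past the threshold. Camera adjusted p was 1.46e-05, 0.00157, 0.00247 and 7.44e-05, and 0.681, 0.681, 0.133 and 0.615 as adjusted p with an estimated correlation. With PWDxPWK replicate 2 as the single array of its genotype these calls were lost (adjusted p = 0.0700 for the piRNA, pachytene and stromal lists and 0.164 for interferon), and without PWD replicate 3 that of interferon was lost (adjusted p = 0.0726).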

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

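The tests of probe mismatch, of germ cell stage and of somatic cells for the 14 X-linked genes, and those of a single array and of stage for the counts against the mid-parent, were chosen only after the results were seen.

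Within B6xBALB/C, 31 sets of 6 values were examined for a sample far from the others, and 5 had one, where chance gives about 1 in 20. Replicate 6 had a sex-body silencing factor score of -0.204 (next 0.036), a spermatid score of -0.211 (next 0.052), a Leydig cell score of 0.392 (next 0.013) and a Cfap74 level of 6.09 (next 7.16). Replicate 4 had a Chrdl1 level of 7.26 (next 7.59). Effects on X-linked genes that differed between hybrids and parents by the interaction test were Nudt10 (1.07), Tsx (0.79), Porcn (0.76), Mpp1 (0.74) and Slc38a5 (0.71), and Magea5 (-1.80), 3830403N18Rik (-1.56), Magea6 (-1.50), Magea3 (-1.13) and Bex1 (-1.09). Probe sets without a single named gene, 2852 past the filter on dim signal and left out of the report's comparisons, gave 50 calls between the reciprocal hybrids, against 5 between the control reciprocal F1s.

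Of 474 X-linked genes 14 were higher in both hybrids than in the parent with the same X, 4.24 times the number for independent lists. Outside the X, chromosomes change from PWD towards B6 in PWDxB6 and from B6 towards PWD in B6xPWD. A probe mismatch in copies there would raise the signal in 1 comparison and lower it in the other. The 14 genes were chosen for a rise in both (median of 0.81 against PWD and 1.04 against B6), so that rise is no test by itself. Mismatch in such copies would not raise their number above that for independent lists. The excess argues against it as the cause for the set, but not for each gene. The pachytene score was 0.000796 higher in B6xPWD than in B6, so as a covariate it decides nothing there. In PWDxB6 it was 0.150 higher than in PWD, against an SD of 0.329 within genotypes. With it as a covariate 97.7% of the median rise was kept in PWDxB6, 94.6% at the lowest without 1 array. All 14 genes stayed past the threshold. The mean of synapsis and recombination genes differed by -0.0472 between PWDxB6 and PWD, and 101.5% was kept with it. Both differences were smaller than the SD within genotypes (0.168 for the synapsis and recombination mean). These covariates could therefore move little, and they do not decide on stage in PWDxB6. For B6xPWD against B6, where the mean of synapsis and recombination genes differed by 0.328, the stage this mean reads is argued against as the whole cause, since 89.6% of the rise was kept with it as a covariate (83.3% at the lowest without 1 array) and 12 of the 14 genes stayed past the threshold. Calls over all genes in that comparison fell from 2503 to 1078 with it. Both scores are rough measures of stage with slopes fitted within genotypes, so they may remove too little of its effect. A difference in the share of somatic cells between B6xPWD and B6 cannot be told apart from genotype. With somatic markers as a covariate the median rise went from 1.04 to 0.752 (72.5% kept) and 2 of the 14 genes stayed past the threshold. Calls over all genes fell from 2503 to 35 with it, so the loss was not particular to these genes. B6 had the highest mean of the 7 genotypes in the Leydig (0.315), endothelial (0.261), stromal (0.184) and Sertoli cell (0.146) lists. B6xPWD had the lowest in the Leydig (-0.133) and endothelial (-0.171) lists. A candidate explanation, incomplete silencing of X-linked genes in spermatocytes, predicted a fall of these genes with the pachytene score within the other genotypes. Instead the median slope was 0.14 against -0.08 for all X-linked genes, at percentile 100 of 10000 random X-linked lists, so the prediction failed. The lists were matched on mean level only, not on expression in germ cells, so germ cell genes can rise with the score either way. The slope therefore does not decide on silencing in the hybrids, and both this and the hybrid genotype stay open.

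B6xPWD had more genes past the threshold against the mid-parent than PWDxB6. A single outlying array as the whole cause is argued against, since the lowest count without a B6xPWD array was 3.93 times the 99 of PWDxB6, but it was 389 of 2135 and came without replicate 2. The role of stage cannot be told apart from genotype, since with the pachytene score as a covariate the ratio of the counts was 2.18, but 1.11 without B6xPWD replicate 2 and 12.1 without PWDxB6 replicate 2. Of 100 drawn splits of the 9 arrays 1, the real one, gave 2135 genes and the highest other gave 98, but other splits mix the parental strains, so chance stays open. With the intra-subspecific F1s as reference the counts were 282 and 130, and a biological difference between the directions of the cross stays open, untested.

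The B6xBALB/C arrays spread along the pachytene score, from -0.543 in replicate 6 to 0.882 in replicate 2. Stage of the germ cells is consistent with this, since their first component (64.9% of variance) correlated at 0.585 across autosomal genes with the slope on the score in the other 6 genotypes. A mislabelled sample stays open, as replicate 6 lay nearer to its own genotype for 3 of 3 X-linked genes that tell the reciprocal F1s apart, too few to decide (exact sign test p = 0.25). The age of the pools in hours and the purity of the preparations are not given in the sources used here, and no biological explanation was tested.

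Other splits of the arrays were counted for each comparison with 3 arrays or more per group. With 3 or 4 genotypes, other splits mix PWD and B6 arrays, which differ in 2719 genes, and this adds to the spread within groups, so those splits do not decide on chance. For the 99 genes of PWDxB6, 3 of 100 drawn splits gave as many. The highest other gave 249, with the B6 arrays as a group of their own, which points to a structure of the samples by strain. For the 1328 genes of the interaction, 1 of 100 gave as many and the highest other was 661, and for its X shift of 0.0248, 82 of 100 gave one as large (highest other 0.155). For the 65 genes of the control cross, 8 of 84 splits gave as many, so chance is not excluded. The highest gave 1261, with B6xBALB/C replicates 1, 2 and 5 against the rest, which points to a structure of these samples along the pachytene score. The remaining comparisons allow 10 splits, too few for a share under 0.05. They gave 418 genes between the reciprocal hybrids (highest other 1, as large in 1 split), 2719 between the parents (highest other 0, as large in 1 split), and X shifts of 0.0381 for PWDxB6 against PWD (highest other 0.0356, as large in 1 split), 0.0645 for B6xPWD against B6 (highest other 0.0966, as large in 5 splits) and 0.0290 between the reciprocal hybrids (highest other 0.0670, as large in 9 splits).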

How the results depend on the processing

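The pachytene covariate was chosen only after the results were seen. For 108 results of named genes, recomputed 1999 times in all, 1749 kept direction and call, 250 kept direction and lost the call, and 0 reversed. Gene lists kept both in 774 of 888 cases. Array signal over background was not analysed here, so dim genes are the least certain. Unless stated, the cause was not tested.

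Without each array in turn, counts ranged from 54 to 626 between the reciprocal hybrids, 30 to 87 for PWDxB6 and 389 to 2433 for B6xPWD against the mid-parent, 1802 to 2341 between parents, 1 to 1011 in the control cross, 0 to 1 for PWDxPWK and 788 to 1544 in the interaction. X shifts ranged from -0.0641 to 0.0186 between the reciprocal hybrids, -0.0536 to 0.0580 in the interaction, 0.0337 to 0.0526 for PWDxB6 against PWD and 0.0168 to 0.112 for B6xPWD against B6. X score differences ranged from -0.0836 to 0.00724 between the hybrids, 0.0903 to 0.110 for PWDxB6 and 0.0925 to 0.183 for B6xPWD against the other genotypes. Without B6xPWD replicate 3 the X shift between the reciprocal hybrids and in the interaction and the score difference between the hybrids turned sign, and without B6 replicate 2 that of the interaction was 0.00478.

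Array weights gave 4635 genes between the reciprocal hybrids, 212 for PWDxB6 (124 higher and 88 lower) and 5967 for B6xPWD against the mid-parent, 1618 in the control cross, 2 for PWDxPWK and 3314 in the interaction, with an X shift of 0.0222 there and of 0.0316, no longer past the threshold, for B6xPWD against B6. A fit of only the groups compared gave 207 (reciprocal hybrids, 40 higher and 167 lower), 174 (PWDxB6, 91 higher and 83 lower), 0 (control) and 3 (PWDxPWK, all lower, without Aldh7a1). The pachytene covariate gave 137 (reciprocal hybrids), 483 (PWDxB6), 1055 (B6xPWD), 1 (control) and 2085 (interaction), and an X shift of -0.0718 between the reciprocal hybrids, which then passed the threshold. With that covariate the medians reversed for synapsis between the reciprocal hybrids (0.0559), pachytene in B6xPWD (-0.0317), between parents (0.0905) and in the control cross (-0.0107), and piRNA between parents (0.0421) and in the control cross (-0.105), in part by construction, since it was built from pachytene genes. With the intra-subspecific F1s as reference, B6xPWD gave 282 genes, and endothelial genes in PWDxB6 (0.0216) and stromal genes in B6xPWD (0.0108) reversed. Autosomal genes tested alone gave 41 for PWDxB6.

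Without the dim filter PWDxPWK gave 2 genes and the X shift between the reciprocal hybrids was 0.000448. With the stricter dim filter the control cross gave 21 genes and the X shift of the interaction was 0.00853. The control cross gave 3 genes with quantile normalization, 27 with trend and robust variances, 1275 with B6xBALB/C replicates 1 to 3 and 0 with replicates 4 to 6. With an estimated correlation the X shifts for PWDxB6 against PWD (0.0381, p = 0.280) and B6xPWD against B6 (0.0645, p = 0.287) kept their size and lost the call.

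The replicate numbers do not pair the arrays, since 17 of 57 same-numbered pairs correlated above 0.1 (range -0.323 to 0.443). With a replicate block the counts were 1044 between the reciprocal hybrids, 239 for PWDxB6 (140 higher and 99 lower), 1311 in the control cross and 4 for PWDxPWK.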

Other observations

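The genes here were chosen only after their values were seen, and no test of an explanation was run. Nnat, a gene expressed from the father's copy, was at the level of the father's strain in both hybrids. Its mean was 7.49 ± 0.09 in PWD and 7.45 ± 0.01 in PWDxPWK, 6.23 ± 0.09 in B6, 6.41 ± 0.16 in PWDxB6 and 7.33 ± 0.09 in B6xPWD (SD, n = 3, and n = 2 for PWDxPWK). Oasl2 was lower in both hybrids (7.58 ± 0.09 and 7.64 ± 0.05) than in B6 (8.03 ± 0.07) and PWD (8.28 ± 0.19), and as low in B6xBALB/C (7.42 ± 0.08, n = 6) and BALB/CxB6 (7.58 ± 0.10, n = 3). Vnn1 was at 6.87 ± 0.06 in B6 but at 8.05 ± 0.13 in B6xBALB/C and 8.25 ± 0.33 in BALB/CxB6.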
